A study of Mus musculus with 6 samples.

How the data were processed

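Messenger RNA was measured by RNA sequencing in activated CD8+ T cells from mouse spleen, in 3 vehicle libraries and 3 libraries treated with blebbistatin, an inhibitor of the ATPase of myosin II. Per the labels' protocols, treated cells received 2 µM for 24 h, total RNA was extracted with TRIzol and chloroform, and libraries were made with a TruSeq RNA kit and sequenced on an Illumina NovaSeq instrument. That kit does not mark the strand of a transcript, so reads of overlapping genes on opposite strands cannot be told apart. Groups and replicate numbers were taken from the labels. The labels do not say whether replicates came from separate animals or cultures, and p-values therefore measure only the spread between these samples, which may be technical. What the vehicle was is also not given in the labels, so whether both groups received the same solvent is not known.

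Per the submitters' processing notes, HISAT2 2.1.0, StringTie 1.3.4 and DESeq2 1.22.2 were used with genome build mm10, with no role or order given. The deposited gene tables have the layout of StringTie's gene abundance output, with 47729 Ensembl genes in each. The TPM values, transcript abundances corrected for length, were made by the authors and sum to 1000000 in each library. The FPKM values, fragments scaled by transcript length and library size, were made by the authors and differ from TPM by 1 factor per library. The deposited coverage is the mean read depth over a gene, with no normalization. Other settings of the authors' pipeline are not given in the sources used here. Between 12 and 14 rows of a library held a gene at more than 1 place, with their TPM and FPKM already summed.

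The values hold no counts, so the test fitted to log values was used. Depth was read from the ratio of coverage to FPKM, which lay between 5.54 and 5.98. In genes of low level the commonest number of aligned bases was 300, taken as 1 fragment read from both ends. On that reading the libraries held between 18500000 and 19900000 fragments. A transcript of 2 kb at 1 TPM then rests on 17.7 to 18.9 fragments, so values near 1 TPM carry a large counting error. No library repeated the TPM values of another.

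Genes with a mean of at least 1 TPM over the 6 libraries were tested, 13372 in all. Blebbistatin was compared with vehicle on log2(TPM + 1) by limma 3.58.1 in R 4.3.3, with empirical Bayes moderation along a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes at low level. The 30 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists. Lists with fewer than 5 tested members would have been described by values only.

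Genes named in the text were chosen by a rule fixed before the data were examined. It took the 10 strongest rises and 10 strongest falls among genes that passed, did not overlap between groups and reached 5 TPM in the higher group, leaving out predicted genes and receptor segments. It added up to 3 members of each list that passed, or the member with the highest level where none did, and a fixed set of T cell and myosin genes. Members of lists and platelet genes named beyond this rule were chosen after their values were seen. One gene that the rule names is not reported here. Gene positions, lengths, GC content and overlaps came from the GENCODE annotation of GRCm38, where 99.1% of the gene identifiers matched and 99.6% of the tested genes had a length and GC value. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

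The test was run first on simulated data with the means and spreads of the 6 libraries. In that simulation of blebbistatin against vehicle, 13230 genes were tested. It recovered 49% of 100 genes changed by 1.5-fold and 87% of 100 genes changed by 2-fold, with 3 false calls. The changed genes were drawn only from those with a mean of at least 5 TPM, so recovery at lower levels was not tested. With no change simulated, 0 of 13243 genes were called. With 1 list shifted by 0.3, camera called that list and 0 others. The simulated genes varied independently of each other, so the simulation does not test the preset correlation of camera. Nor does it test false calls from a trend that many genes of a library share.

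Alternatives were fixed beforehand for the pseudocount, the minimum level, FPKM, median-ratio and quantile scaling, the trend and robust options of limma, a block on replicate number and leaving out each library. A loess correction for transcript length and GC content in each library and a restriction to protein-coding genes were added after the data were seen. Tests that need counts had also been planned and were not run.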

Results

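Gene expression was measured by RNA sequencing in activated CD8+ T cells from mouse spleen after 24 h with vehicle (3 libraries) or with 2 µM blebbistatin (3 libraries), which blocks the ATPase of myosin II, the motor that contracts actin filaments. The series addressed how a chemical modulator of the cytoskeleton affects these cells. The libraries held an implied 18500000 to 19900000 fragments each, and the depths of the groups overlapped. Pearson correlations of log2(TPM + 1) were 0.990 to 0.991 among vehicle libraries, 0.983 to 0.989 among blebbistatin libraries and 0.978 to 0.988 between the groups. The first principal component held 42.8% of the variance. Vehicle libraries lay at -15.5, -13.4 and -16.4 on it, while blebbistatin 1 lay at 30.5, blebbistatin 2 at 0.23 and blebbistatin 3 at 14.5. In all 6 libraries the T cell receptor beta segments were diverse, with 22 or 23 Trbv segments at 1 TPM or more, and Trbv13-2, the segment with the highest level, held 11.1% to 11.97% of the Trbv total.

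In the blebbistatin libraries 14 of 31 target genes of the tumour suppressor p53, 4 of 23 naive and memory genes and 3 of 8 erythroid, platelet and stromal markers, all of platelets, were higher than with vehicle, and 4 of 36 genes of glycolysis and hypoxia were lower. Of these lists, that of p53 targets passed camera with an estimated correlation (adjusted p = 0.033), while those of naive and memory genes (adjusted p = 0.12), of erythroid, platelet and stromal markers (adjusted p = 0.11) and of glycolysis (adjusted p = 0.11) did not. The genes with the strongest rises were Mcam, an adhesion molecule, from 2.57 ± 0.318 to 9.17 ± 0.858 TPM (mean ± SD, n = 3 in each group here and below), and Ppbp, a platelet chemokine, from 13.1 ± 2.00 to 38.4 ± 1.64 TPM. Plk2, a kinase induced by p53, rose from 7.51 ± 0.362 to 18.6 ± 0.662 TPM. The strongest falls among genes that met the naming rule were Sapcd2, which acts on spindle orientation, from 22.9 ± 2.25 to 11.6 ± 0.777 TPM, and Cdkn2a, a cell cycle inhibitor locus, from 5.91 ± 0.840 to 2.76 ± 0.404 TPM. Myh9, the main nonmuscle myosin II heavy chain in these cells and a direct target of the drug, stood at 371 ± 22.5 TPM with vehicle and 377 ± 29.4 TPM with blebbistatin.

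By limma with Benjamini-Hochberg adjustment, 244 of 13372 genes changed, 187 higher and 57 lower with blebbistatin, and 224 of them were protein-coding. The median log2 fold change was 0.59 among the higher genes and -0.47 among the lower ones. At least 2-fold changes were found in 22 genes, 19 higher and 3 lower. The 3 lower ones were the microRNA loci Mir5130, Mir6996 and Mir3074-1, which are short and at low level. The groups did not overlap in 31.0% of tested genes, where chance gives 10% on average over groupings. Genes vary together across libraries, so a single grouping can lie far from that average. After a correction for transcript length and GC content, added after the data were seen, 446 genes passed, 265 higher and 181 lower, so the share of higher genes was 59.4% in place of 76.6%. The count rested on the set of libraries, with 13, 11 and 7 genes passing without vehicle 1, 2 and 3, and 120, 1090 and 3 without blebbistatin 1, 2 and 3. Without blebbistatin 2 falls outnumbered rises, with 496 higher and 594 lower, and with 27 higher and 82 lower among 109 genes at 2-fold or more. The direction of all 244 genes was kept in each of those fits, but they had been picked in these same libraries, so a change of sign was unlikely beforehand.

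**Figure D1:**
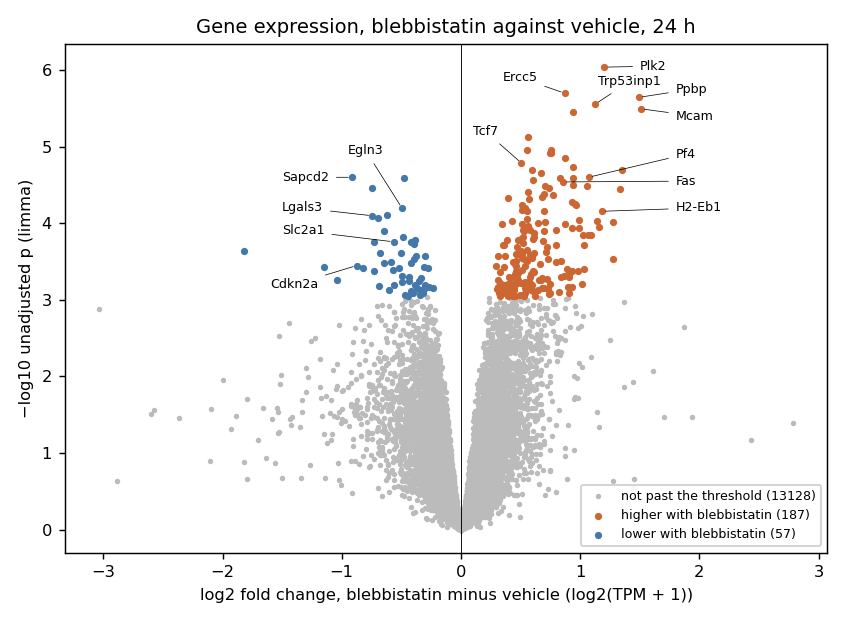
Each point is 1 of the 13372 genes tested, with the log2 fold change of blebbistatin minus vehicle on the x axis and the negative log10 of the unadjusted limma p on the y axis. Orange points are the 187 genes that rose and blue points the 57 that fell at an adjusted p under 0.05.

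Other genes with strong rises were Robo3, a guidance receptor (log2 fold change 1.33, SE 0.15), H2-Eb1, an MHC class II chain (1.18, SE 0.15), and Ak1, an adenylate kinase (1.16, SE 0.15). Timp3, a metalloproteinase inhibitor, rose by 1.14 and Bcl2l2, a survival protein of the BCL2 family, by 1.06. Exons of Timp3 and Bcl2l2 overlap those of other genes over 21.3% and 13.3% of their length, and their values are uncertain to that extent. Among the falls were Ankle1, an endonuclease (-0.75), Lgals3, a galectin (-0.75), Mdk, a growth factor (-0.73), Map6, a microtubule protein (-0.70), and Emilin2, an extracellular matrix protein (-0.68). Nfkbid, an atypical inhibitor of NF-kappaB, fell from 27.1 ± 1.34 to 16.9 ± 1.59 TPM. Mir5121 (-0.82) is covered by exons of Rpl13a, Snord33 and Gm45713 on the same strand, so its reads cannot be told apart from theirs. Snora41 (-0.73), a small nucleolar RNA, lies inside Eef1b2 with no exon overlap. Adjusted p over these genes by limma with Benjamini-Hochberg lay between 0.0158 and 0.0388. The positions in GRCm38 are chromosome 9, 44134469 to 44142727 for Mcam, chromosome 13, 110395044 to 110400844 for Plk2 and chromosome 2, 25372321 to 25378213 for Sapcd2, all protein-coding.

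Of 31 p53 target genes tested, 14 rose and 0 fell, and 21 were higher and 1 lower when adjusted over the list alone. Trp53inp1, which promotes p53-dependent cell death, rose from 67.5 ± 3.89 to 149 ± 15.3 TPM (log2 fold change 1.13, SE 0.09, adjusted p = 0.0079 by limma with Benjamini-Hochberg). Ercc5, a DNA repair nuclease, rose from 17.6 ± 0.549 to 32.9 ± 0.694 TPM, and Fas, a death receptor, from 32.2 ± 1.21 to 59.4 ± 6.94 TPM. Mdm2, the ubiquitin ligase that limits p53, rose from 86.0 ± 5.74 to 120 ± 5.53 TPM. Ccng1, Psrc1, Ei24, Pmaip1, Zmat3, Btg2, Sesn2, Perp, Tnfrsf10b and Plk2 were the other members that rose. Cdkn1a, a cell cycle inhibitor and p53 target, stood at 300.4 ± 9.61 against 369 ± 33.2 TPM and did not pass (adjusted p = 0.092), and Bax, a death effector, was at 345 and 346 TPM. Over all genes, 3 members rose without vehicle 1, 2 or 3 and 0 without blebbistatin 3, with 20 or 21 higher when adjusted over the list alone in each of these fits. The list median was 0.48, with 0.54, 0.42 and 0.42 in blebbistatin 1, 2 and 3 against the vehicle mean. Camera gave this list an adjusted p of 5.0e-12, and it was the only list of the 30 to pass with an estimated correlation (adjusted p = 0.033). Among 26 apoptosis regulators 3 rose and 0 fell, and 6 were higher when adjusted over the list alone. These were Fas, Birc3, an inhibitor of apoptosis (0.36), and Bcl2a1b, a survival gene with close paralogs and an exon overlap of 49.1% (0.56). Camera placed the apoptosis list higher (adjusted p = 0.0088; adjusted p = 0.17 with an estimated correlation).

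**Figure D2:**
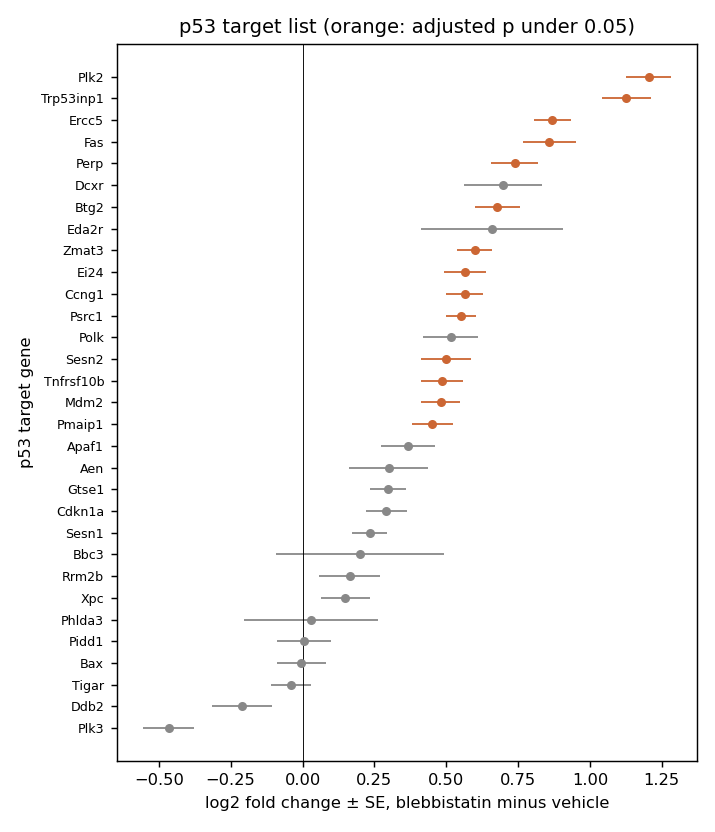
Log2 fold change with its standard error for each of the 31 p53 target genes tested, blebbistatin minus vehicle (3 libraries each). Orange points mark the 14 genes that passed, and 27 of the 31 values are above 0.

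Naive and memory genes included 4 that rose and 0 that fell among 23 tested, with 12 higher and 4 lower when adjusted over the list alone. Tcf7, a transcription factor of naive and memory T cells, rose from 186 ± 5.92 to 264 ± 8.53 TPM. Dapl1 rose from 70.8 ± 4.29 to 131 ± 12.8 TPM and Il7r, the interleukin 7 receptor, from 57.1 ± 1.81 to 81.6 ± 7.24 TPM. Of the 23 log2 fold changes 17 were above 0 and 6 below, so the list did not move as 1. Among the 6 was Klf2 (-0.82), at 22.1 ± 1.69 against 12.4 ± 3.82 TPM (adjusted p = 0.086 by limma with Benjamini-Hochberg). The camera adjusted p was 0.0016 (adjusted p = 0.12 with an estimated correlation). For 22 inhibitory receptor and exhaustion genes, 0 passed over all genes and 8 were higher when adjusted over the list alone. Ctla4, an inhibitory receptor, stood at 192 ± 1.67 against 247 ± 21.8 TPM (adjusted p = 0.054 by limma with Benjamini-Hochberg), and Pdcd1 at 10.7 ± 0.717 against 11.7 ± 0.945 TPM. That list had a median of 0.23, or 0.11 with a pseudocount of 5, and a camera adjusted p of 0.00058 (adjusted p = 0.10 with an estimated correlation).

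The cytotoxic effector genes did not pass as a list. Of 29 cytotoxic genes 2 rose, Serpinb6b, a granzyme inhibitor of the serpin family (0.70), and Zeb2, a transcription factor (0.93, from 0.647 to 2.14 TPM), and 3 were higher when adjusted over the list alone (camera adjusted p = 0.17). Gzmb, the main cytotoxic protease, stood at 7040 ± 91.3 against 6164 ± 334 TPM (adjusted p = 0.11 by limma with Benjamini-Hochberg), Prf1 at 7.81 ± 0.419 against 8.05 ± 0.233 TPM and Ifng at 16.2 ± 0.737 against 18.2 ± 2.24 TPM. Ifng shares 25.9% of its exon length with an overlapping gene. Among 31 activation genes Cd69 rose (0.49) and Nfkbid fell, with 2 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.71). Among 25 cytokines and chemokines Tnfsf8, the CD30 ligand, rose (0.46) and Osm, oncostatin M, fell (-0.38), and the counts were the same when adjusted over the list alone (camera adjusted p = 0.71). Of 20 T cell identity genes, Thy1, a surface glycoprotein, fell from 1416 ± 21.4 to 1170 ± 36.0 TPM, with 2 lower when adjusted over the list alone (camera adjusted p = 0.92). Cd8a was at 412 ± 3.01 and 429 ± 3.49 TPM and Cd3e at 315 ± 25.3 and 302 ± 9.21 TPM, and neither passed.

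**Figure D3:**
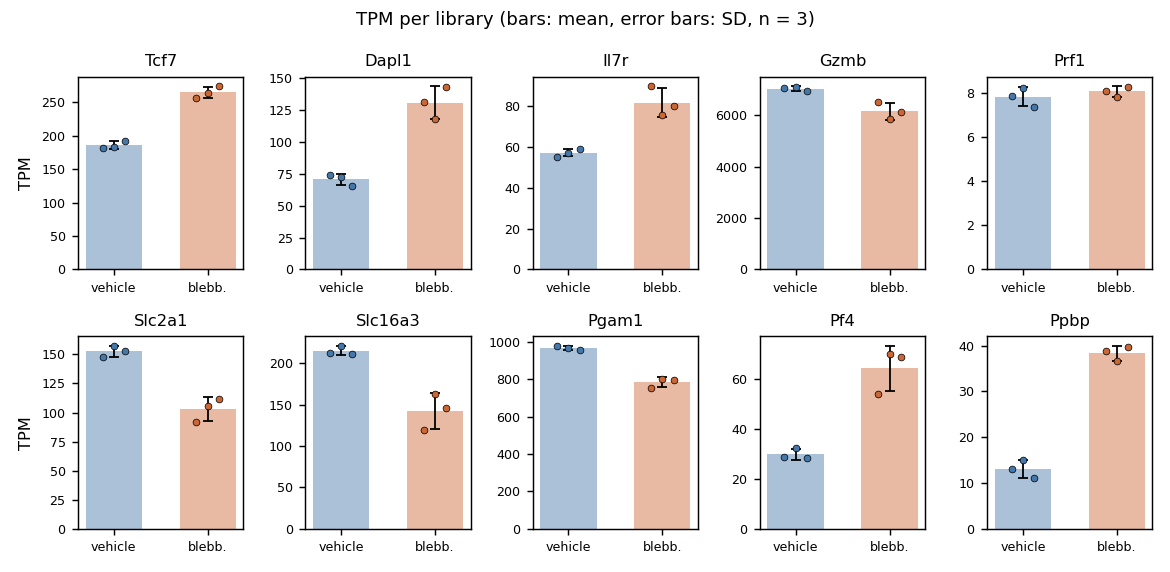
TPM of 10 genes in each library, with bars at the mean of 3 libraries and error bars of 1 SD, for naive and memory genes, cytotoxic genes, glycolysis genes and platelet genes. Tcf7, Dapl1, Il7r, Pf4 and Ppbp were higher and Slc2a1, Slc16a3, Pgam1 and Gzmb lower in each blebbistatin library than in each vehicle library, although Gzmb did not pass.

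Genes of glycolysis and hypoxia included 4 that fell and 0 that rose among 36 tested, with 12 lower when adjusted over the list alone. Slc2a1, the glucose transporter GLUT1, fell from 153 ± 4.97 to 103 ± 10.4 TPM, and Slc16a3, a lactate exporter, from 215 ± 5.51 to 142 ± 22.1 TPM. Pgam1, a glycolytic mutase, fell from 968 ± 12.6 to 786 ± 27.8 TPM and Egln3, a hypoxia-induced prolyl hydroxylase, from 102 ± 1.85 to 71.9 ± 4.29 TPM. The list median was -0.16 and the camera adjusted p 1.9e-06 (adjusted p = 0.11 with an estimated correlation). In the MYC and ribosome biogenesis list of 33 genes, Mybbp1a fell (-0.35) and 1 was higher and 9 lower when adjusted over the list alone (median -0.11, camera adjusted p = 2.6e-05; adjusted p = 0.10 with an estimated correlation). Of 24 cholesterol synthesis genes Tmem97 (-0.33) and Insig1, which restrains sterol synthesis (-0.31), fell, with 4 lower when adjusted over the list alone (camera adjusted p = 0.0017; adjusted p = 0.10 with an estimated correlation). Of 28 heat shock and unfolded protein genes Xbp1, a transcription factor (-0.37), and Hyou1, a chaperone (-0.34), fell, with 4 lower when adjusted over the list alone (camera adjusted p = 0.0015; adjusted p = 0.12 with an estimated correlation). The 16 NRF2 and aryl hydrocarbon receptor targets had a median of -0.13, with 0 passing over all genes, 1 lower when adjusted over the list alone and Txn1 at -0.06 (camera adjusted p = 0.0015; adjusted p = 0.10 with an estimated correlation).

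Both cell cycle lists were lower by camera at the preset correlation. Among 48 DNA replication genes 0 passed, either over all genes or adjusted over the list alone, while the list median was -0.11 and the camera adjusted p 1.8e-06 (adjusted p = 0.10 with an estimated correlation). Pcna, the replication clamp, stood at 944 ± 7.503 against 830.4 ± 17.4 TPM. Among 44 mitosis and cytokinesis genes Cdca8, a chromosomal passenger subunit, fell (-0.31), and 4 were lower when adjusted over the list alone (median -0.03, camera adjusted p = 0.00058; adjusted p = 0.12 with an estimated correlation). That median ran from -0.0017 with quantile scaling to -0.14 after the length and GC correction. Mki67, a proliferation marker, was at 261 ± 14.9 and 252 ± 16.8 TPM and did not pass, while after the length and GC correction its log2 fold change was -0.22 (adjusted p = 0.028 by limma with Benjamini-Hochberg).

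Type I interferon genes were higher as a list. Of 36 tested, 2 rose and 0 fell, 9 were higher when adjusted over the list alone, and the median was 0.22 (camera adjusted p = 2.0e-06; adjusted p = 0.11 with an estimated correlation). Mx1, an antiviral GTPase, rose from 11.1 ± 2.33 to 22.8 ± 0.302 TPM and Gbp5, a guanylate-binding protein, from 41.6 ± 1.198 to 55.2 ± 3.92 TPM. Of 28 NF-kappaB targets Tnip3 (0.68), Cd83 (0.61) and Birc3 rose, with 4 higher when adjusted over the list alone (camera adjusted p = 0.58). Of 29 integrated stress response genes Atf3 (0.52) and Sesn2 (0.50) rose, with 3 higher when adjusted over the list alone (camera adjusted p = 0.73).

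Genes of the drug's target pathway did not pass. Among 19 nonmuscle myosin II genes and regulators 0 passed over all genes or adjusted over the list alone, and the median of 0.03 had the opposite sign to the camera direction (adjusted p = 0.71). Myh10 was at 5.14 ± 0.339 and 5.33 ± 0.986 TPM, Cfl1, an actin-severing protein, at 2844 ± 54.5 and 2719 ± 62.7 TPM, and Myh14 was listed at 0 in each library except blebbistatin 1. Of 25 SRF and MRTF targets Dstn, an actin-depolymerizing protein, rose (0.53), and it alone was higher when adjusted over the list alone (camera adjusted p = 0.34). Of 8 YAP and TEAD targets Axl (0.60), Ptpn14 (0.62) and Asap1 (0.46) rose, the same number as when adjusted over the list alone (camera adjusted p = 0.015; adjusted p = 0.27 with an estimated correlation). That call was lost with no minimum level (adjusted p = 0.065) and without blebbistatin 2 (adjusted p = 0.13). Of the 23 YAP and TEAD list members present in the data, those below the minimum level included Ctgf, at 0 TPM in each library, Cyr61 and Ankrd1. Of 38 adhesion and migration genes 3 rose, among them Itga4 (0.45) and Itgb3 (1.03), with 4 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.71). Itgb3 is also the beta subunit of the platelet fibrinogen receptor.

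Of the marker lists of other cell types, those of platelets and of B cells were higher by camera at the preset correlation, and neither call held with an estimated correlation. Of 8 erythroid, platelet and stromal markers the 3 platelet genes Pf4, a platelet chemokine, Ppbp and Itga2b, a platelet integrin, rose, with 4 higher when adjusted over the list alone (camera adjusted p = 0.0029; adjusted p = 0.11 with an estimated correlation). Pf4 rose from 29.9 ± 2.21 to 64.2 ± 9.04 TPM, and it lies beside Ppbp on chromosome 5, at 90772435 to 90773383 in GRCm38. Platelet genes outside the fixed lists, chosen after their values were seen, that also rose were Parvb (1.28), Treml1 (0.99), Clu (0.90), Vwf (0.87) and Plek (0.54). Besides the 7 platelet genes first seen to rise, 25 further platelet markers were tested, of which Plek and Itga2b passed, and 18 of the 25 values were above 0 and 7 below, among them F2rl3 (-0.24) and P2ry12 (-0.19). Of 9 B cell markers H2-Eb1 and Igkc, the immunoglobulin kappa constant segment (0.80), rose, with 5 higher when adjusted over the list alone (median 0.52, or 0.17 with no minimum level, camera adjusted p = 0.0016; adjusted p = 0.12 with an estimated correlation). Markers of CD4 and regulatory T cells (8 tested, median 0.05), myeloid cells (6 tested, 0.14), neutrophils and mast cells (5 tested, 0.00) and NK cells (7 tested, 0.13) had 0 members past the threshold and camera adjusted p of 0.71, 0.41, 0.71 and 0.71. Adjusted over the list alone, these lists had 1, 3, 0 and 1 members higher and 0, 0, 0 and 1 lower. Cst3, Mcpt8 and Eomes, the members with the highest level in the myeloid, neutrophil and mast cell, and NK lists, had log2 fold changes of -0.24, -0.08 and -0.33. Eomes is also in the naive and memory list, so its level does not mark NK cells alone. The median and mean differed in sign for the myosin II, cytokine, integrated stress response, T cell identity and neutrophil lists.

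Mitochondrial transcripts took 6.58% to 6.89% of TPM in vehicle libraries and 9.14%, 7.21% and 7.33% in blebbistatin 1, 2 and 3. Of 15 mitochondrially encoded genes 0 passed, either over all genes or adjusted over the list alone, and mt-Co1 stood at 15988 ± 113 against 20089 ± 2201 TPM (adjusted p = 0.091 by limma with Benjamini-Hochberg). Camera placed the list higher (adjusted p = 0.0017; adjusted p = 0.66 with an estimated correlation), and its median of 0.20 was 0.10 without blebbistatin 1 and 0.07 after the length and GC correction. For 56 nuclear genes of oxidative phosphorylation 0 passed, also when adjusted over the list alone, and the median was -0.05 (camera adjusted p = 0.077), with Atp5b at -0.05.

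**Figure D4:**
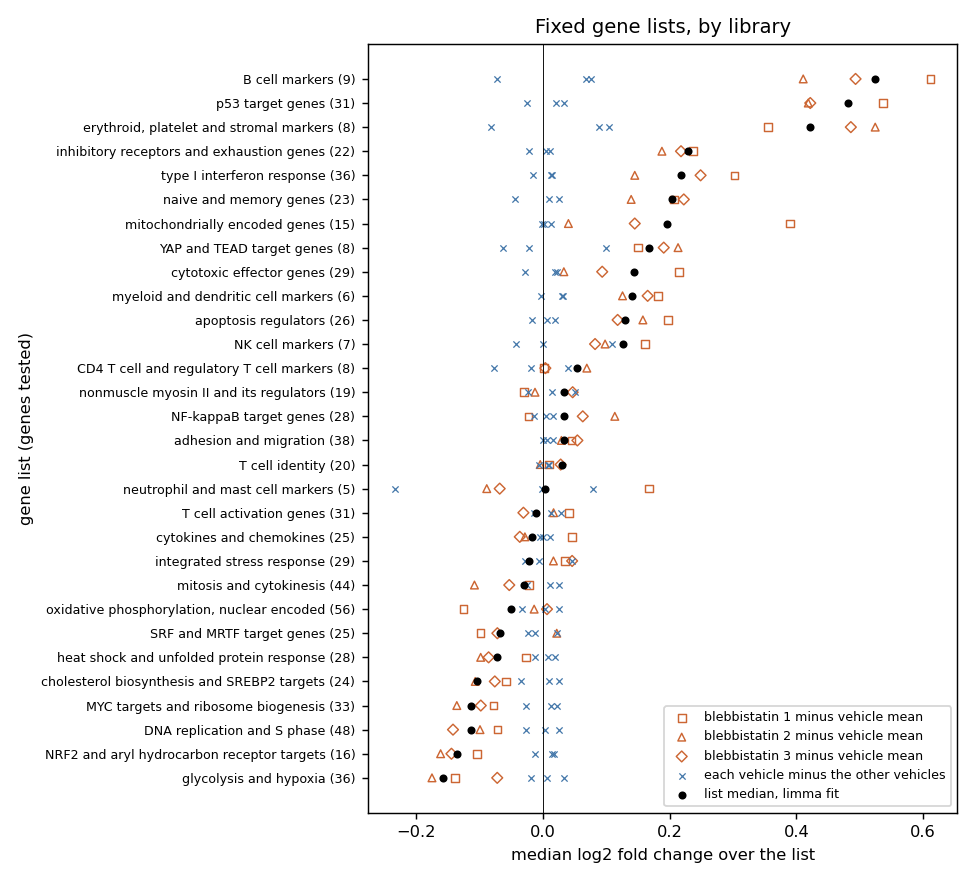
Median log2 fold change of each of the 30 fixed gene lists, with the number of genes tested in brackets. Open orange symbols give each blebbistatin library against the vehicle mean, blue crosses each vehicle library against the other vehicle libraries, and black points the fitted median; the p53 list lies at 0.54, 0.42 and 0.42 in the 3 blebbistatin libraries.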

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

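The test on cell cycle withdrawal, the test on platelet markers with a low baseline and the test on a lower share of T cells were chosen only after the results they bear on had been seen. Genes below the minimum level, which the comparison did not use, were detected more often with blebbistatin. Of 34357 such genes, 7492.0 ± 81.7 had a TPM above 0 with blebbistatin and 6869 ± 179 with vehicle (mean ± SD, n = 3), and each blebbistatin library lay above each vehicle library.

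The rise of p53 target genes was set against 3 explanations. After the correction for transcript length and GC content the list median was 0.41, and after median-ratio scaling 0.45, each above 0.24, which is 50% of the uncorrected 0.48, by more than the bootstrap standard errors of 0.06 and 0.09. The correction left 18 of 31 members higher and 0 lower. Withdrawal from the cell cycle stays open. The DNA replication list had a median of -0.11, which is small beside 0.48, but the bound for this test was set after the values were seen. No value here shows how far replication genes would fall on withdrawal, and both cell cycle lists were lower by camera at the preset correlation. A p53 response to the drug remains a hypothesis, found and tested on the same data. Damage to the cells, light, the solvent and differences in culture were not tested.

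The rise of platelet genes was set against more platelet or megakaryocyte RNA and against a lower share of T cells. For the first, 25 platelet markers outside the 7 defining genes had a median of 0.27 (bootstrap SE 0.10). Among these 25 were Itga2b and Plek, which are named above as rising and so are not independent of the pattern. The median lay under the bound written beforehand of 50% of the 1.03 of the 7 defining genes. That bound was wrong and decides nothing, because the 7 genes had been picked for their rise. In addition, 12 of the other markers stood at 5 TPM or more in vehicle libraries, where a small amount of platelet RNA would be hidden. A further test was chosen after this was seen. In it, 17 of 29 markers under 5 TPM (58.6%) were higher in each blebbistatin library than in each vehicle library. That was so for 9.07% of 14711 other genes under 5 TPM, and for a mean of 12.3% in 10000 draws matched on level. Of these draws 0 reached 17. The draws took genes independently, while markers of the same source can move together across the libraries. For a set that moves together chance gives 5%, so the draws overstate the evidence. A fall in T cells that raised other cell types alike stays open. The median of the 25 markers lay 0.26 above that of myeloid and neutrophil markers with an SE of 0.17, but the 12 markers at 5 TPM or more limit this comparison too. The B cell markers had a median of 0.52 (0.17 to 0.59 over the settings). Platelet RNA in the cultures may contribute and also stays open, as does expression of these genes by the T cells, which was not tested.

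The distance of blebbistatin 1 from the vehicle libraries, with blebbistatin 2 near them on the first component, went with GC content. Across genes, which are not independent replicates, the difference between blebbistatin 1 and blebbistatin 2 had a Spearman rho of -0.56 with GC and 0.10 with transcript length. Against the vehicle libraries rho with GC was -0.54, -0.07 and -0.29 in blebbistatin 1, 2 and 3. The main comparison carried the trend too. Its log2 fold changes had a rho of -0.40 with GC and 0.14 with transcript length. A trend of library preparation is a candidate explanation for part of the distance. After the correction blebbistatin 1, 2 and 3 lay at 23.0, 4.67 and 14.8 on the first component. An unequal response to the drug cannot be told apart from this, because the p53 list median of blebbistatin 1 was 1.28 times that of blebbistatin 2, between the bounds set for either answer.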

How the results depend on the processing

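The length and GC correction and the protein-coding restriction were chosen after the data were seen. Against 244 genes, 49 passed with no minimum level, 160 without the trend and 446 after the length and GC correction, and leaving out 1 library gave 3 to 1090. Against 22 genes at 2-fold or more, a pseudocount of 0.1 gave 40, a pseudocount of 5 gave 3, no minimum 8, a minimum of 5 TPM 11 and FPKM 10, and leaving out 1 library gave 3 to 109. With no minimum 24825 genes were tested, which raises the adjustment; otherwise the cause was not tested. Of 30 lists, 16 passed camera and 1 with an estimated correlation, with 11 at an unadjusted p under 0.05. The estimate lay under the preset 0.01 for inhibitory receptors (-0.029), NRF2 targets (-0.024) and cholesterol synthesis (-0.0035). These lists therefore did not lose their call through a higher correlation. For other lists the estimate lay above 0.01, among them the mitochondrially encoded genes (0.86). Fry, which does not compare a list with other genes, also passed 16, among them adhesion (adjusted p = 0.011) and myeloid markers (0.0048), which camera did not pass, and not mitosis (0.055) or the mitochondrially encoded genes (0.25). Same-numbered libraries did not deviate together (r of 0.01, -0.04 and -0.03), and under the replicate block by limma 0 genes passed, 0 at 2-fold, with 2628 at an unadjusted p under 0.05 against 3065, and 17 lists passed. The 244 genes, where tested, kept their direction in each setting, which says little because they were picked in the same libraries. Of the 16 lists, 15 kept their call in each camera setting at the preset correlation in which they were tested. The erythroid, platelet and stromal list was not tested at a minimum of 5 TPM or with FPKM. List medians that moved by over 1.5 times, as ranges over the settings, were those of mitosis (-0.14 to -0.0017), inhibitory receptors (0.11 to 0.28), B cell markers (0.17 to 0.59), erythroid, platelet and stromal markers (0.097 to 0.47), naive and memory genes (0.11 to 0.25), heat shock (-0.13 to -0.049), cholesterol (-0.13 to -0.065) and NRF2 targets (-0.18 to -0.088), besides the YAP and mitochondrially encoded lists (0.036 to 0.22 and 0.071 to 0.26). Some genes that did not pass did so elsewhere, with adjusted p by limma of 0.013 for Cdkn1a, 0.024 for Pcna, 0.028 for Mki67 and 0.032 for Ctla4 after the length and GC correction, 0.041 for Gzmb with quantile scaling, and 0.048 with FPKM and 0.043 with protein-coding genes only for Ctla4. So did Cdkn1a and Gzmb without blebbistatin 1, and Ctla4, Pcna, mt-Co1 and Cst3 without blebbistatin 2. Some genes turned sign. Myh9 was -0.0086 with median-ratio scaling, and Myh10 -0.032 with quantile scaling and -0.067 after the correction. With quantile scaling Atp5b was 0.012, Prf1 -0.013 and Mki67 0.0095. Over the libraries left out Myh9 ran from -0.030 to 0.082, Myh10 from -0.038 to 0.17, Atp5b from -0.12 to 0.010 and Mcpt8 from -0.20 to 0.0082. Tests that need counts were not run. At about 18 fragments for 1 TPM in a 2 kb transcript, small changes of low genes may have been missed, and recovery by level was not tested. For the 244 and the 22 genes, 10 splits of 3 against 3 are too few for a share under 0.05; the highest of the other splits gave 1 and 1.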
